A study of Lacticaseibacillus casei str. Zhang with 5 samples.

How the data were processed

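Gene expression was measured on 5 arrays, all on 1 slide and from 1 scan: 1 of lag phase (2 h), 2 of late logarithmic phase (9 h) and 2 of stationary phase (14.5 h) in soymilk. The stationary arrays lie in one row of the slide and the other arrays in the other row, so position and stage cannot be told apart there. Groups and replicate numbers were taken from the labels. Per the file headers, the arrays were read with Agilent Feature Extraction 10.5.1.1 in a single Cy3 channel. The processed signal is an intensity on a linear scale that, per the file headers, was background-subtracted and detrended for each spot, with surrogate values where a spot did not stand above background. The authors also deposited a value table, which was found to hold the same intensity rounded to 3 significant digits. It differed from the processed signal of the same spot by at most 0.497% and was not centred or scaled between arrays. Its column medians were 379 at 2 h, 9.80 and 10.4 at 9 h, and 157 and 186.5 at 14.5 h.

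The arrays hold 14998 gene spots for 6763 probes of 60 bases, of which 6740 are spotted 2 times and 23 are spotted 66 times. The 536 control spots and the spots with an outlier flag (54 to 100 per array) were left out, and the remaining spots of a probe were averaged. No gene spot was saturated on any array (0 spots). Between 0 and 2 of the 77 negative control spots per array were well above background. The median SD between copies of a probe ran from 0.0620 to 0.0829 on the log2 scale.

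The probes carry 0 gene names, 0 descriptions and 0 coordinates in the files. The gene table used for names lists 2890 genes of another strain, assembly ASM82905v1, without sequences, and 0 probes matched it. Gene level therefore means probe level, and the 29 lists of functional gene groups fixed before the data were examined could not be matched to probes and were not tested. The comparisons, tests, gene lists and rule for named genes were set before the data were examined, except where a later choice is stated. The rule asked for the 8 largest rises and falls per comparison among probes that passed the test with the same sign in every pair of arrays. With no names, it was shortened to 2 rises and 2 falls and limited to block 2 and to probes well above background on every array of both stages. That limit was set after the data were seen.

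Blocks of probe numbers were found after the data were seen, by placing 4 change points along the probe numbers where detection on the 9 h arrays changed. A probe was counted as detected on an array where the Feature Extraction flag marks it as well above background.

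From the deposited intensity, log2 values were computed and each array's 75th percentile was subtracted. Under 50% of the probes were detected on the 9 h arrays (45.9% and 43.7%), so the percentile was taken over the 2727 probes well above background on all 5 arrays. Of these, 2536 are in block 2, 88 in block 1, 59 in block 3 and 44 in block 4. The plan named no set of probes for the percentile, and the set detected on all arrays was chosen after detection had been seen. The percentile over all probes was tried as an alternative, also after the data were seen. A probe was tested where it was well above background on every array of at least 1 stage, which left 4839 probes.

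Stages were compared with limma 3.58.1 in R 4.3.3, with a mean per stage over all 5 arrays and moderated variances (lmFit and eBayes). There were 2 residual degrees of freedom and 1.40 prior degrees of freedom. The spread at 2 h is assumed to equal that of the other stages, since only 1 array was available there. Adjusted p-values are Benjamini-Hochberg values over the probes tested, with a threshold of 0.05, and differences are on the log2 scale. For block 1 probes not well above background on both 9 h arrays, a lower bound of the fold was given. Counts, medians and ranges of differences cover all tested probes, including values not well above background.

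The fit was tested on 20 sets of simulated arrays per comparison with the real means of the 4839 probes, in which 200 probes were changed. With the moderated SDs of the real data, 2-fold changes were recovered on average for 26.4%, 24.1% and 55.4% of the probes so changed, for 9 h against 2 h, 14.5 h against 2 h and 14.5 h against 9 h. For 4-fold changes the recovery was 77.5%, 78.8% and 85.5%, and false calls made up 5.17%, 4.38% and 3.84% of the calls. With the sample SDs in place of the moderated ones, 2-fold changes were recovered for 31.1%, 30.5% and 44.5%, and 4-fold changes for 58.5%, 60.0% and 68.2%. False calls made up 5.00%, 5.52% and 5.70%. In the real data a far larger share of probes was called (84.1%, 39.3% and 83.3% of those tested). The simulations also held no error of scaling. These rates therefore check the fit and do not estimate recovery or false calls in the real data.

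The alternatives were quantile normalization, median centring, normexp background correction (offset 50), the deposited value table, other filters on dim probes, the replicate number as a block, the arrays of the compared stages alone, eBayes with trend and robust settings, a 2-fold threshold, limma's treat against a 1.5-fold change, and each 9 h or 14.5 h array left out in turn. Sequence comparisons used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and Benjamini-Hochberg values outside limma used statsmodels 0.14.6.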

Results

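The study followed Lacticaseibacillus casei Zhang, a lactic acid bacterium used as a probiotic, while it fermented soymilk that had been supplemented with glucose. Total RNA was taken in lag phase at 2 h (pH 6.4), in late logarithmic phase at 9 h (pH 5.2) and in stationary phase at 14.5 h (pH 4.5). Labelled RNA from each sample was hybridised to a 1-colour array with 6763 probes of 60 bases. There was 1 array for lag phase, 2 for late logarithmic phase and 2 for stationary phase. The 9 h and 14.5 h arrays are labelled as replicates of their stage, and the label text mentions 2 biological replicates. Because the titles leave open whether the numbered arrays came from separate cultures, the p-values measure only the spread between these samples. The number of arrays limits the precision, and the lag phase has no replicate check. The files do not pair the probes with genes, so changes are given per probe, by probe ID and sequence, with no gene names or genome positions.

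Signal stood well above background for 4764 of the 6763 probes at 2 h, for 3107 and 2955 on the 9 h arrays, and for 4581 and 4650 on the 14.5 h arrays. Ordered by probe number, the probes fell into 5 blocks that differed in where signal was found. Block 2 (numbers 1995 to 4808, 2814 probes) was well above background for 96.9% of its probes at 2 h, for 98.1% ± 0.980 (SD, n = 2) at 9 h and for 91.4% ± 1.71 (SD, n = 2) at 14.5 h. Block 1 (numbers 1 to 1994) was well above background for 95.1% of its probes at 2 h and 95.4% on each 14.5 h array, but for 8.07% and 4.56% on the 9 h arrays. Block 3 (numbers 4809 to 6713, 1905 probes) was near background throughout, with 4.09% to 6.35% of its probes well above it on the 5 arrays. All 44 probes of block 4 were well above background on every array. Of the 6 probes of block 5, 2 were well above background on the 2 h and 14.5 h arrays and 0 on the 9 h arrays. Block 1 carried 73.8% of the summed gene-probe signal at 2 h, 7.67% ± 0.0829 (SD, n = 2) at 9 h and 82.7% ± 1.15 (SD, n = 2) at 14.5 h. Block 2 carried 22.4%, 86.4% ± 0.476 and 13.6% ± 1.11 of it. Relative to the block 2 median, the block 1 median lay at 2.22 on the log2 scale at 2 h and at 4.20 and 3.88 on the 14.5 h arrays; on the 9 h arrays most block 1 probes give only a bound. The comparisons below lead with block 2, the large block with signal at every stage, and give block 1 separately. Which block belongs to the labelled strain is not known. In both comparisons with 9 h, stage cannot be told apart from the presence of block 1 signal. The blocks were found after the data were examined.

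**Figure D1:**
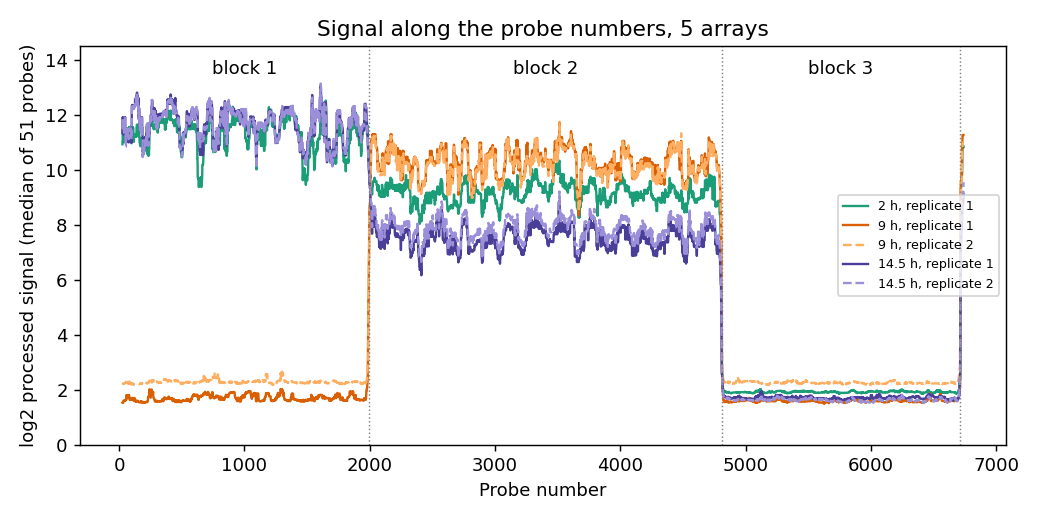
Running median of log2 processed signal over 51 neighbouring probes (vertical axis) against probe number (horizontal axis), 1 line per array, with dotted lines at the last probe of blocks 1, 2 and 3. In block 1 the 9 h arrays lie near the level of block 3 (medians of 1.66 and 2.27 in log2), while the other arrays lie above 11 (medians of 11.36 to 11.73).

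The first comparison asked which transcripts differed between late logarithmic and lag phase. Of the 2769 block 2 probes tested, 789 were higher and 1254 lower at 9 h than at 2 h after Benjamini-Hochberg adjustment of limma's test. Estimated changes were at least 2-fold for 428 of the higher and 754 of the lower probes, and at least 4-fold for 145 and 204. Of the 2769 probes, 2536 were detected on all arrays. For the others, values not well above background enter these counts. The middle 90% of block 2 differences ran from -2.32 to 2.08 on the log2 scale, with a median standard error of 0.12. Among block 2 probes with signal on both sides, cust_02607 (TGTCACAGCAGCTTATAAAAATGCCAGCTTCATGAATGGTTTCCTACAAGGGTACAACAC) rose most, by 6.96 ± 0.41 (SE) on the log2 scale, or 125-fold (adjusted p = 0.000548). It was followed by cust_02435 (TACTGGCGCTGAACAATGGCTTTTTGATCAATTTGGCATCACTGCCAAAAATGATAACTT), which rose by 5.43 ± 0.15 (adjusted p = 0.000172). The largest falls were at cust_03896 (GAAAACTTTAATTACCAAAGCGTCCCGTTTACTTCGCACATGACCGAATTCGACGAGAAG), with a log2 difference of -6.64 ± 0.12 (adjusted p = 0.000123), and at cust_03471 (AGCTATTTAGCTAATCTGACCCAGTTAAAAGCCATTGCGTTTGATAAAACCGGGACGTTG), with -6.63 ± 0.20 (adjusted p = 0.000174). Block 1 gave 1893 lower and 6 higher of 1909 probes tested. For the 1733 block 1 probes that were not well above background on both 9 h arrays, normalised signal at 2 h was at least 448-fold higher at the median in the main scaling. The bound was 175-fold on unscaled signal, 82.5-fold with normexp background correction, 73.9-fold with the percentile over all probes and 19.1-fold with quantile normalization. It sets the 2 h value against the lowest signal well above background on each 9 h array, or the probe's own signal where that was higher. Over all blocks, 824 probes were higher and 3245 lower of 4839 tested in the main scaling, but 2728 higher and 1928 lower with the percentile over all probes and 2850 and 1666 with quantile normalization. The direction within block 2 depends on the scaling. Of the calls, 38.6% were higher with the percentile taken over probes detected on all arrays, 97.9% with the percentile taken over all probes and 98.4% with quantile normalization over all probes. The settings over all probes use every block 1 probe, most of them at background at 9 h. The share was 46.7% with median centring, 35.9% with block 2 scaled alone and 48.4% with quantile normalization of block 2 alone. Over all settings run, the log2 difference ran from 6.67 to 10.55 for cust_02607, from 4.80 to 9.56 for cust_02435, from -6.73 to -4.04 for cust_03896 and from -6.72 to -3.43 for cust_03471.

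The next comparison set stationary phase against lag phase, the last stage against the first. In block 2, 302 probes were higher and 645 lower at 14.5 h than at 2 h. Estimated changes were at least 2-fold for 120 and 178 of these. The middle 90% of block 2 differences ran from -1.10 to 0.95. The largest rises were at cust_03685 (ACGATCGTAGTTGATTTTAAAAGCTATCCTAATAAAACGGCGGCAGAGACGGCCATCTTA), by 4.16 ± 0.23 (SE) on the log2 scale (adjusted p = 0.0130), and at cust_03839 (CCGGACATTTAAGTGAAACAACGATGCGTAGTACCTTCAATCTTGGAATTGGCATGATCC), by 4.16 ± 0.19 (adjusted p = 0.0130). The largest falls were at cust_03471, with -3.13 ± 0.20 (adjusted p = 0.0134), and at cust_03223 (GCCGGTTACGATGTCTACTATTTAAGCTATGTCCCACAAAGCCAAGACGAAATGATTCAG), with -2.73 ± 0.29 (adjusted p = 0.0177). On the same scale, which is set mostly by block 2, 869 block 1 probes were higher and 2 lower at 14.5 h, with a median log2 difference of 1.44. The spread in this test comes in part from the 9 h arrays, where most block 1 probes were at background. The median SE was 0.39 in block 1 and 0.12 in block 2, so the block 1 count also reflects arrays outside the comparison. With block 1 scaled to its own percentile, which centres it by construction, 718 were higher and 800 lower. The calls rest on both stationary arrays: with either left out, limma called 0 block 2 probes, while 753 and 813 had an unadjusted p under 0.05, the lone array being assumed to vary like the 9 h pair. Of the block 2 calls, 31.9% were higher in the main scaling, 72.5% with normexp background correction, 8.51% with quantile normalization and 4.11% with the percentile over all probes. The share was 34.5% with median centring, 39.4% with block 2 scaled alone and 45.5% with quantile normalization of block 2 alone. Over all settings run, the log2 difference ran from 3.53 to 5.02 for cust_03685, from 3.53 to 5.29 for cust_03839, from -5.49 to -2.84 for cust_03471 and from -3.36 to -1.16 for cust_03223, whose smallest fall came with normexp.

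Stationary and late logarithmic phase each had 2 arrays, so this comparison is the only one with replicates on both sides. In block 2, 1086 probes were higher and 902 lower at 14.5 h than at 9 h. Estimated changes were at least 2-fold for 495 and 331 of these, and at least 4-fold for 118 and 91. The largest rises were at cust_03896, by 6.26 ± 0.10 (SE) on the log2 scale or 76.5-fold (adjusted p = 4.12e-05), and at cust_03852 (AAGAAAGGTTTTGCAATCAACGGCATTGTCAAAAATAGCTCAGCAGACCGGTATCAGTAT), by 5.93 ± 0.14 (adjusted p = 6.37e-05). The largest falls were at cust_02607, with -6.61 ± 0.33 (adjusted p = 0.000316), and at cust_02435, with -5.16 ± 0.12 (adjusted p = 6.41e-05). In block 1, 1908 of 1909 probes were higher at 14.5 h. For the 1736 block 1 probes not well above background on both 9 h arrays, normalised signal at 14.5 h was at least 1463-fold higher at the median in the main scaling. The bound was 226-fold on unscaled signal, 247-fold with normexp background correction, 156-fold with the percentile over all probes and 31.6-fold with quantile normalization. Of the block 2 calls, 54.6% were higher in the main scaling, 70.0% with normexp background correction, 0.328% with quantile normalization and 0.585% with the percentile over all probes. The share was 44.9% with median centring, 62.0% with block 2 scaled alone and 49.6% with quantile normalization of block 2 alone. Over all settings run, the log2 difference ran from 3.03 to 6.41 for cust_03896, from 2.23 to 6.08 for cust_03852, from -10.32 to -6.15 for cust_02607 and from -9.43 to -3.99 for cust_02435.

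**Figure D2:**
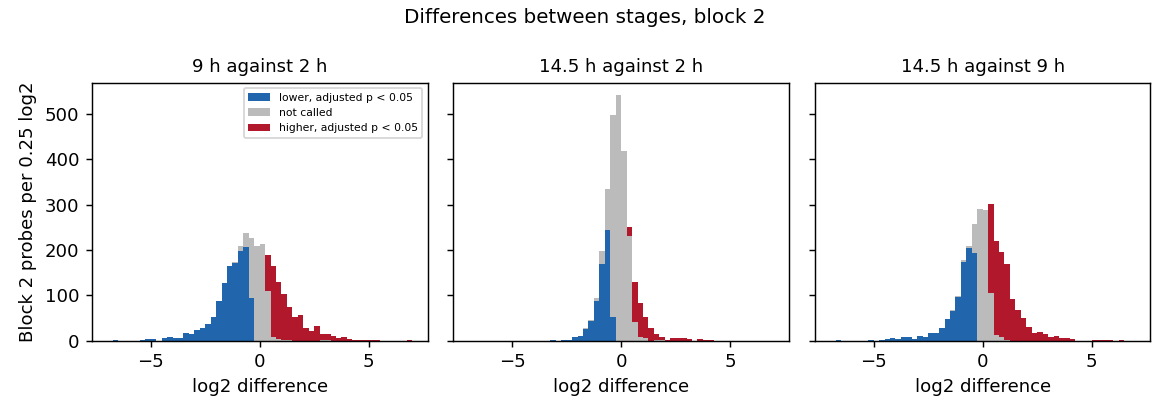
Histograms of log2 differences between stages for the 2769 block 2 probes tested, in bins of 0.25 log2 units, with 1 panel per comparison. Blue and red mark probes called lower and higher by limma at an adjusted p under 0.05, and grey the others; the middle panel, 14.5 h against 2 h, is the narrowest, with 90% of probes between -1.10 and 0.95.

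Across the 3 stages, in the main scaling, 948 block 2 probes were lowest at 9 h, called lower than at 2 h and lower than at 14.5 h. Another 692 were highest at 9 h by the same criteria. These counts depend on the scaling: they were 9 and 2562 with the percentile over all probes, 7 and 2648 with quantile normalization over all probes, and 862 and 856 with quantile normalization of block 2 alone. In the main scaling, independent lists of the same sizes would share 492 and 257 probes. Both comparisons use the same 9 h arrays. With a different 9 h array in each comparison, 703 and 744 probes were lowest at 9 h (326 and 335 for independent lists) and 610 and 606 highest (217 and 208), the lone array being assumed to vary like the 14.5 h pair. Simulated unchanged stages gave 0 probes of either kind, but with a median of 0 calls in each comparison they do not measure what the shared arrays add. For example, cust_03896 lay at 6.17 on the normalised log2 scale at 2 h, at -0.46 ± 0.02 (SD, n = 2) at 9 h and at 5.79 ± 0.10 (SD, n = 2) at 14.5 h. The reverse held for cust_02607, at -1.87, 5.09 ± 0.14 and -1.52 ± 0.58. Over the 2536 block 2 probes detected on all arrays, the 2 h array correlated with the 14.5 h arrays at Pearson's r = 0.945 and 0.949 and with the 9 h arrays at 0.810 and 0.815. The 9 h and 14.5 h arrays correlated with each other at 0.869 to 0.874, and the replicates at 0.996 (9 h) and 0.998 (14.5 h). These correlations run across probes, which are not independent replicates.

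**Figure D3:**
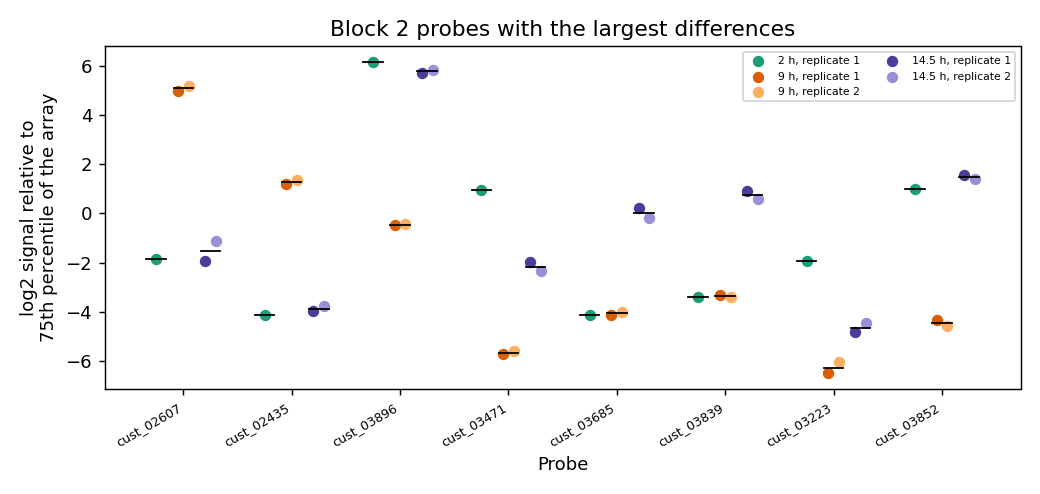
Normalised log2 signal (vertical axis, relative to the 75th percentile of each array) of the 8 block 2 probes named in the text, with 1 point per array and a black line at each stage's mean. The probe cust_02607 stands at 5.09 at 9 h against -1.87 at 2 h and -1.52 at 14.5 h, and cust_03896 shows the opposite order.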

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

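The sequence tests and the estimate of cross-hybridisation were chosen after the signal had been seen; the tests of neighbouring spots and of the brighter probes were set before their results were seen.

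Signal appeared in block 1, outside the block of probes detected at every stage: 95.1% of its probes were well above background at 2 h and 95.4% at 14.5 h, against 6.32% on the 9 h arrays, while the labels describe 1 strain at all stages. Uneven hybridisation is argued against by position, because dim block 1 spots and bright block 2 spots lie side by side. On the 9 h arrays, 4562 and 4561 block 1 spots touched a bright block 2 spot, and 3862 and 4016 of them were not well above background. The share itself, 86.4%, follows largely from the definition of block 1 by low detection on those arrays. Regulation of genes within a single genome is argued against too: the sequence boundary lay at probe 1994, 0 probes from the signal boundary. That sequence boundary is where the probe sequences changed along the probe numbers, by 4-base words learned from probes up to 1500 and from 2500 to 4300. It was searched for only between 1500 and 2500, so a boundary in that range was bound to be found, but its place was not fixed. It does not reflect GC content, whose mean differed between blocks 1 and 2 by less than its SD within either block. A part of that genome with its own kind of sequence was not tested separately. A candidate explanation is RNA of an organism other than that of block 2 on the 2 h and 14.5 h arrays. This rests on 4-base words, which told held-out probes of blocks 1 and 2 apart. The balanced accuracy, the mean of the shares placed correctly in each block, was 75.8%. For the first and second part of block 2 it was 50.6%. The organism was not determined for either block, so which block belongs to the labelled strain is unknown. Whether a mixed culture, mixed RNA or a wrong label brought the signal stays open and untested.

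Block 2 profiles of the 2 h and 14.5 h arrays were closer to each other than to the 9 h arrays, the same split of arrays as in block 1. Dim probes near the floor are argued against: in the brighter part of block 2, r with the 2 h array was higher for the 14.5 h than for the 9 h arrays by 0.311. Block 1 RNA binding to block 2 probes stays open: by cross-hybridisation at the strength seen on the 9 h arrays, 2.66% of block 1 probes would reach the lower quartile of block 2 at 2 h and 5.62% at 14.5 h, but binding in the other direction was not measured. Growth stage also stays open, as does a difference between the samples that goes with the block 1 signal, and the stages and that signal are confounded here.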

How the results depend on the processing

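The percentile over all probes, both settings on block 2 alone, the unscaled bounds and the use of a different 9 h array in each comparison were chosen after seeing the data; the other settings were planned. No difference changed sign for the named probes under any setting run, though sizes moved with scaling and background correction, and 204 of their values kept their side of the threshold. The other 12, all for 14.5 h against 2 h, lost it with a stationary array left out or with the replicate block.

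For 9 h against 2 h, the total of 4069 calls became 2262 on probes detected on all arrays, and 2043 block 2 calls became 1182 with a 2-fold minimum and 1255 with treat. The median log2 bound of block 1 at 2 h over 9 h, 8.81, became 4.26 with quantile normalization, 6.37 with normexp, 6.21 with the percentile over all probes and 7.45 unscaled.

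For 14.5 h against 2 h, the total of 1902 calls became 2977 with normexp, 1165 without the filter on dim probes, 1224 with a 2-fold minimum and 575 with treat. The 947 block 2 calls became 1680 with quantile normalization, 418 without the filter, 1475 on probes detected on all arrays, 298 with a 2-fold minimum, 139 with treat, 1897 with the percentile over all probes, 1490 on block 2 alone and 1479 on block 2 alone with quantile normalization. The difference between stages in the block 1 minus block 2 median, 1.82, became 1.58 with quantile normalization and 1.50 with normexp. With 1 array left out, the total ran from 0 to 2406 and the block 2 count from 0 to 898, at 0 without either stationary array.

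For 14.5 h against 9 h, the total of 4031 became 2254 on probes detected on all arrays, and 1988 block 2 calls became 826 with a 2-fold minimum and 953 with treat. The median log2 bound of block 1 at 14.5 h over 9 h, 10.51, became 4.98 with quantile normalization, 7.95 with normexp, 7.29 with the percentile over all probes and 7.82 unscaled. Stricter thresholds lower counts by construction, as does omitting block 1 probes. The percentile over all probes shifts every probe of an array alike, as given below. For the other settings the cause was not tested.

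Quantile normalization and the percentile over all probes moved the block 2 median from -0.29 to 3.51 and 2.31 (9 h against 2 h) and from 0.09 to -4.08 and -3.14 (14.5 h against 9 h).

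With the replicate number as a block, block 2 calls were 1551 for 9 h against 2 h, 0 for 14.5 h against 2 h (832 at an unadjusted p under 0.05; 0 calls over all probes) and 1541 for 14.5 h against 9 h. Deviations of same-numbered arrays correlated at 0.0505 over 2 pairs. That gives no sign that the numbers pair the samples, but 2 pairs cannot exclude it.

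The brightest probe per gene and the gene lists were not run (no gene names), nor a slide or scan block (1 slide, 1 scan). Probes not well above background give bounds only.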

Other observations

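The tests of block 1 on its own scale and of neighbouring probes were chosen after the data were seen.

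Scaled to its own 75th percentile on the 3 arrays that show it, block 1 also differed between 2 h and 14.5 h. Of 1888 probes, limma called 718 higher and 800 lower at 14.5 h, and the middle 90% of log2 differences ran from -1.78 to 2.12. The even split follows from the scaling. This fit has a single pair of replicates, at 14.5 h.

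Blocks 1 and 3, and blocks 2 and 3, also differed in sequence: 4-base words told held-out probes apart at a balanced accuracy of 77.2% and 75.1%. For the first and second part of block 1 the balanced accuracy was 47.1%. The sequence boundary between blocks 2 and 3, searched for only between 4300 and 5300, lay at probe 4813, 5 probes from the signal boundary at 4808.

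The hypothesis that probe numbers follow gene order within block 2, so that neighbours change together, was not borne out: Pearson's r between neighbours for 14.5 h against 9 h was -0.00941 over 2723 pairs, and it was -0.00229 and 0.00235 for 9 h and 14.5 h against 2 h. The correlation runs across probes, which are not independent replicates.

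Block 2 probes with a single open frame among the 3 forward reading frames were compared with each other. Those whose frame encodes a hydrophobic segment were set against the rest, in the hypothesis that hydrophobic ones fall from 9 h to 14.5 h. The median difference was -0.00415 on the log2 scale for 124 against 1473 probes (permutation test, two-sided, p = 0.97, adjusted p = 0.97 over 3 comparisons). The check is void, because only 57.7% of the tested block 2 probes have a single open frame, under the 80% required.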
